A study of Mus musculus with 20 samples.

How the data were processed

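RNA sequencing was done in RAW264.7 cells, with 20 libraries in 10 groups of 2. Per the labels, the authors checked the reads with FastQC, aligned them with STAR 2.5.3a to GRCm38 (mm10) and compared groups with DESeq2 1.16.1. The authors deposited a table of read counts per gene and a table of RPKM. The RPKM deposited equal the counts divided by gene length and library total, so they add no independent data. The counting tool and the strand setting are not given in the sources used here, so values of overlapping or antisense genes and of multigene families such as histones, Ifit and Gstt genes are uncertain. Symbols came from the deposited file for 42745 of 50686 genes and from GENCODE M21 for 7915, while 26 had none. Library totals of 19051780 to 62313792 counts set the precision; counting intervals are 95% exact binomial, floors are 3 counts over a group, and both cover counting error only.

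Counts were analysed with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr by group (16042 genes tested), a mean per group over 20 libraries (10 residual degrees of freedom), robust quasi-likelihood fits and F tests, and Benjamini-Hochberg adjustment over the tested genes of a comparison. A gene was called at adjusted p under 0.05. In total 18 comparisons were made. Gene lists were fixed from general knowledge, 19 in number; 18 were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison, and the list of markers of non-myeloid cell types held too few measured genes. Comparisons, lists, fixed genes, tests and most alternatives were chosen before the data were examined. Overlaps with shared RANKL libraries were set against 20 simulated draws of unchanged groups, whose equal-size lists were designed after the calls were known; the draws held 3, 3 and 2 calls. Figures were drawn with matplotlib 3.10.9.

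The genes to be named were set by rule: the fixed genes in every comparison (18 were measured), the 4 largest rises and 4 largest falls among called genes with a mean CPM of at least 5 and separated libraries, and up to 4 called members of each list. This rule gives 1101 pairs of gene and comparison, 900 of them called. The report prints a part: the fixed genes, the largest rise and the largest fall, and the largest called member of each printed list, less 3 selected genes (2 of them fixed) that are left out of the text without a replacement. Printed lists are the 2 with the lowest camera p in a comparison, plus each remaining list once where its p is lowest. This reduction was set after values had been seen, and it uses rank alone. It replaced a selection made by hand after leave-one-out values had been seen, which had favoured calls and lists that hold. Of the 900 called pairs 381 (42.3%) are lost when 1 library is left out, against 45 of 176 printed (25.6%) and 336 of 724 not printed (46.4%). The printed genes are therefore steadier than those the rule gives. Over all comparisons camera called 182 of 324 list tests, 41 of them also with an estimated correlation.

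The library number was checked for pairing: deviations from the group mean correlated between libraries of the same number in all 45 pairs of groups (0.221 to 0.596, median 0.454). The labels name no batch, but sample names number all libraries 1 before all libraries 2. The number entered as a block only in an alternative (replicate block), whose biological coefficient of variation was 0.0751 against 0.162 in the main fits. These may thus miss changes. Further alternatives were RLE size factors, no low-count filter, a CPM of at least 1 in at least 4 libraries, fits without robust estimation, DESeq2 1.42.0, only the libraries of a comparison, limma on the log2 RPKM plus 1 or 0.1 (RPKM of at least 1 in at least 2 libraries) and leaving out each library. Chosen after the data were seen were the fits without 5 rRNA-related genes, untreated library 2 left out together with the replicate block, camera with an estimated correlation and the block, effects from libraries of different number, overlap draws with the block, and the reference hour of the remaining RANKL response. A fit with 1 library left out keeps 1 library in that group, which is assumed to vary like the others. It also leaves that group 1 library number, so the difference between numbers enters its comparisons and can end calls. Simulations changed 200 of 16042 genes 1.5-fold, 2-fold or 4-fold in RANKL plus I-BET against RANKL at 24 hours. Of these, 3, 104 and 150 were found, with 0, 3 and 6 false calls. The data held 4299 calls, so power there may differ.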

Results

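Gene expression was measured by RNA sequencing in RAW264.7 cells, a mouse monocyte and macrophage line that forms osteoclasts when it receives the cytokine RANKL. Untreated cells stood for hour 0. The treated cells received RANKL (50 ng per ml), the BET bromodomain inhibitor I-BET (500 nM) or both, for 4, 14 or 24 hours. These 10 groups held 2 libraries each, 20 in all. Total counts per library ran from 19051780 to 62313792. Untreated library 1 was the smallest and untreated library 2 held 10.1% of its counts in 5 genes related to ribosomal RNA, against 0.37% to 1.19% in the other 19 libraries. Every value below rests on n = 2 libraries per group, changes are log2 fold changes with their standard error (SE), and adjusted p comes from edgeR, or for lists from camera, which sets them above or below other genes. The block fits the library number as well. A number in brackets after a gene called with this replicate block, or lost with 1 library left out, is its adjusted p there. A number marked log2 is an effect size. Within the list means adjusted over the list alone, given where it differs, estimated means camera with an estimated correlation, and blocked that with the block. RPKM plus 1 or 0.1 means limma on these values, where the added number shrinks changes at low RPKM and so can enlarge a difference between effects. Untreated cells exist at hour 0 only, so the time in culture and the treatment cannot be separated in comparisons with them. The description field of the untreated libraries begins with a 4 whose meaning is not stated. Nothing in the labels says that the libraries of a group come from separate cultures, so the p-values measure the spread between these samples. The printed fixed genes are Myc, Brd2, Brd3, Hexim1, Nfatc1, Fos, Irf8, Bcl6, Acp5, Ctsk, Mmp9, Dcstamp, Ocstamp, Atp6v0d2, Csf1r and Tnfrsf11a, and those with no SE in a comparison did not pass there.

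Gene positions refer to build mm10 (GRCm38). Myc (ENSMUSG00000022346) lies on chromosome 15, 61985341 to 61990374. Nfatc1 (ENSMUSG00000033016) lies on chromosome 18, 80606205 to 80713071. Acp5 (ENSMUSG00000001348) lies on chromosome 9, 22126731 to 22135746. Ctsk (ENSMUSG00000028111) lies on chromosome 3, 95499286 to 95509362. Mmp9 (ENSMUSG00000017737) lies on chromosome 2, 164940780 to 164955850. Irf8 (ENSMUSG00000041515) lies on chromosome 8, 120736358 to 120756694. Brd2 (ENSMUSG00000024335) lies on chromosome 17, 34112023 to 34122634.

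**Figure D1:**
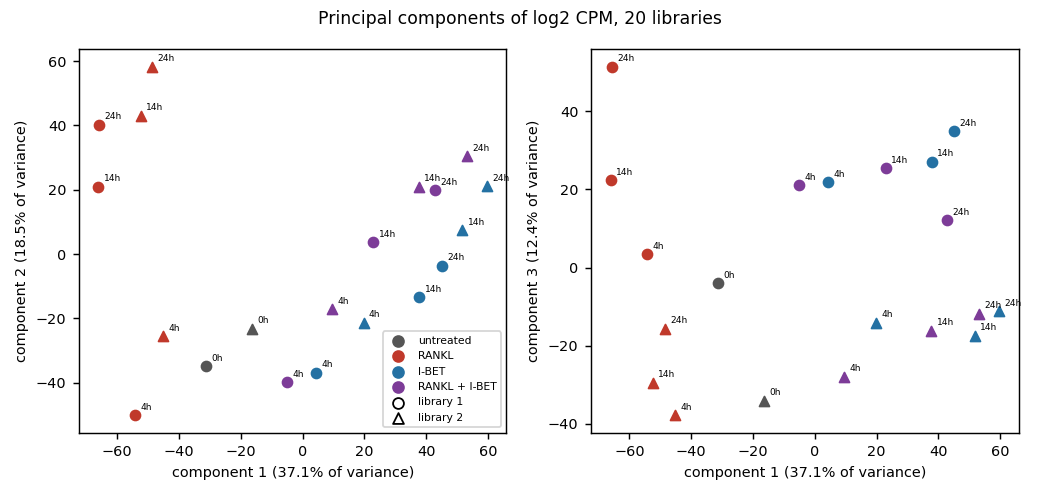
Principal components of log2 CPM in 20 libraries, with component 1 (37.1% of variance) against component 2 (18.5%) and against component 3 (12.4%). Colours stand for treatment and shapes for the library number, which component 3 separates in 10 of 10 groups.

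It was first asked how cells change as RANKL starts osteoclast formation. After 4 hours of RANKL 334 genes rose and 293 fell against untreated cells (1078 and 1247 with the block). The count became 399 and 155 without untreated library 1 and 2, and 241 and 271 without RANKL library 1 and 2. Of these calls 53.3% were higher, and the split was 419 and 185 by limma on RPKM plus 1, 375 and 181 on RPKM plus 0.1 and 505 and 580 by DESeq2. Myc, a transcription factor of growth and proliferation, rose by 3.75 (SE 0.34, adjusted p = 4.79e-05) and Fos, an AP-1 subunit needed for osteoclast formation, rose by 1.62 (SE 0.28, adjusted p = 0.00508). Dcstamp, a membrane protein of cell fusion, rose by 1.17 (SE 0.29, adjusted p = 0.0406) and Ocstamp, a membrane protein of osteoclast fusion, rose by 1.91 (SE 0.28, adjusted p = 0.00131). Traf1, an adaptor of TNF receptor signalling, rose by 3.02 (SE 0.33, adjusted p = 0.000134) and Rpph1, the RNA of ribonuclease P, which has no poly(A) tail, fell by 6.62 (SE 1.44, adjusted p = 0.0186, -2.19 without untreated library 2). Insig1, a regulator of cholesterol synthesis, fell by 1.16 (SE 0.24, adjusted p = 0.0142). The replicate block called Brd3 (0.0168), Nfatc1 (3.03e-06), Irf8 (0.000881) and Tnfrsf11a (0.0486). DESeq2 called Nfatc1 and Mmp9, and the unfiltered fit called Nfatc1 and Mmp9. Leaving out 1 library ended calls: without untreated library 1 for Dcstamp (0.0814), untreated library 2 for Fos (0.107), Dcstamp (0.389), Rpph1 (0.574) and Insig1 (0.142), RANKL library 1 for Dcstamp (0.113), Rpph1 (0.163) and Insig1 (0.149), RANKL library 2 for Dcstamp (0.214), Rpph1 (0.162) and Insig1 (0.0528). Of 49 calls under the naming rule, 28 were lost this way. Calls also ended for Dcstamp with only these libraries, RPKM plus 0.1 and the block without untreated library 2, for Rpph1 with only these libraries, RPKM plus 1 (log2 -4.34), RPKM plus 0.1 and the block without untreated library 2 (log2 -1.73). The NF-kB feedback and target genes list (20 genes, median 1.22) held 14 higher and 0 lower (16 and 0 within the list), above other genes (adjusted p = 1.55e-21, blocked 0.0544), while 8 passed without untreated library 2. Next, the cholesterol synthesis list (21 genes, median -0.77) held 0 higher and 12 lower (0 and 18 within the list), below other genes (adjusted p = 6.12e-18, estimated 0.0717), while 3 passed without untreated library 2 and 5 without 2 others. Camera called 10 of 18 lists, 5 also when estimated.

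By 14 hours of RANKL 1333 genes rose and 1615 fell against untreated cells (3068 and 2759 with the block). Calls numbered 1861 and 1571 without untreated library 1 and 2, and 1894 and 1814 without RANKL library 1 and 2. Higher calls made up 45.2%, while the split was 1267 and 1211 by limma on RPKM plus 1 and 1273 and 1260 on RPKM plus 0.1. Myc rose by 4.20 (SE 0.35, adjusted p = 3.04e-06) and Brd2, a BET protein, rose by 0.24 (SE 0.080, adjusted p = 0.0479). Acp5, tartrate-resistant acid phosphatase, rose by 1.96 (SE 0.42, adjusted p = 0.0047) and Mmp9, a matrix metalloproteinase of osteoclasts, rose by 6.55 (SE 0.64, adjusted p = 1.85e-05, on 6 untreated counts, 11.87 without untreated library 2, which leaves 0 counts). Dcstamp rose by 1.47 (SE 0.29, adjusted p = 0.00301) and Ocstamp rose by 1.54 (SE 0.28, adjusted p = 0.00138). Ifrd2, a gene of the ribosome list, rose by 1.01 (SE 0.19, adjusted p = 0.00219) and Irf8, a transcription factor of the macrophage lineage, fell by 2.86 (SE 0.34, adjusted p = 5.26e-05). Csf1r, the receptor of M-CSF, fell by 0.58 (SE 0.15, adjusted p = 0.0135) and S1pr1, a receptor of sphingosine phosphate, fell by 6.05 (SE 0.43, adjusted p = 1.15e-06). Fcgr3, an Fc receptor, fell by 3.20 (SE 0.23, adjusted p = 1.21e-06). Blocked by replicate, calls were added for Nfatc1 (1.56e-06), Fos (0.0049), Ctsk (0.0225) and Atp6v0d2 (2.92e-08). DESeq2 called Nfatc1 and Fos, and the unfiltered fit called Nfatc1, Fos and Atp6v0d2. Calls that 1 library decided were lost without untreated library 1 for Brd2 (0.167), untreated library 2 for Brd2 (0.237), Acp5 (0.072), Dcstamp (0.0542) and Csf1r (0.101), RANKL library 1 for Brd2 (0.0756) and Csf1r (0.121), RANKL library 2 for Brd2 (0.349). Nfatc1 passed without untreated library 1 (adjusted p = 0.0457). The naming rule gives 73 calls here, and 34 were lost this way. Further calls ended for Brd2 with only these libraries, RPKM plus 1 or 0.1, no filter, RLE factors, the CPM filter, 5 rRNA-related genes left out and the block without untreated library 2. The list of MYC targets in ribosome biogenesis and nucleotide synthesis (38 genes, median 0.64) held 29 higher and 0 lower (32 and 0 within the list), above other genes (adjusted p = 1.64e-17). The macrophage identity list (22 genes, median -1.55) held 0 higher and 18 lower, below other genes (adjusted p = 2.34e-14, estimated 0.053). Of 18 lists camera called 11, 1 also when estimated.

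At 24 hours of RANKL 1290 genes rose and 1742 fell against untreated cells (3002 and 2899 with the block). With 1 library left out, calls numbered 1954 and 1730 without untreated library 1 and 2, and 2037 and 2349 without RANKL library 1 and 2. While 42.5% of the calls were higher, the split was 1557 and 1255 by limma on RPKM plus 1 and 1544 and 1301 on RPKM plus 0.1. Myc rose by 3.39 (SE 0.34, adjusted p = 7.89e-06) and Brd2 rose by 0.27 (SE 0.080, adjusted p = 0.0291). Acp5 rose by 3.25 (SE 0.44, adjusted p = 0.000117) and Ctsk, the bone-resorbing protease cathepsin K, rose by 1.82 (SE 0.17, adjusted p = 3.94e-06). Mmp9 rose by 7.96 (SE 0.64, adjusted p = 2.25e-06, on 6 untreated counts, 13.25 without untreated library 2, which leaves 0 counts) and Dcstamp rose by 1.17 (SE 0.29, adjusted p = 0.0118). Ocstamp rose by 1.42 (SE 0.28, adjusted p = 0.00223) and Atp6v0d2, a proton pump subunit of osteoclasts, rose by 2.40 (SE 0.62, adjusted p = 0.0141). Gstt4, a glutathione transferase, was at least 79.2-fold higher by its 95% counting limit (423 counts against 0, 97.8-fold at a floor of 3, adjusted p = 9.52e-05). Gart, an enzyme of purine synthesis, rose by 0.70 (SE 0.11, adjusted p = 0.000455). Irf8 fell by 3.60 (SE 0.35, adjusted p = 6.49e-06) and Bcl6, a repressor of osteoclast genes, fell by 1.12 (SE 0.17, adjusted p = 0.000362). Csf1r fell by 0.81 (SE 0.15, adjusted p = 0.00151) and Tgfbi, a secreted matrix protein, was lower with a ratio of 424 between the groups (counting interval 75.5 to 16800, 294 counts against 1, adjusted p = 1.25e-06). Cx3cr1, the fractalkine receptor, fell by 4.43 (SE 0.25, adjusted p = 8.69e-08). Calls added by the replicate block were Nfatc1 (log2 0.927, 1.4e-05). The unfiltered fit called Nfatc1. Calls were lost without untreated library 1 for Brd2 (0.128), untreated library 2 for Brd2 (0.192), Dcstamp (0.14) and Atp6v0d2 (0.147), RANKL library 1 for Brd2 (0.0583), Dcstamp (0.0827) and Atp6v0d2 (0.075), RANKL library 2 for Brd2 (0.177). Among 77 calls of the naming rule 30 were lost this way. Other alternatives ended calls for Brd2 with only these libraries, no filter and the block without untreated library 2, for Ocstamp with only these libraries. Next, the macrophage identity list (22 genes, median -2.17) held 0 higher and 20 lower (0 and 21 within the list), below other genes (adjusted p = 1.3e-20, blocked 0.0552). The list of MYC targets in ribosome biogenesis and nucleotide synthesis (38 genes, median 0.47) held 23 higher and 0 lower (27 and 0 within the list), above other genes (adjusted p = 6.14e-12), while 12 passed without untreated library 2 and 14 without untreated library 1. In all 12 of 18 lists passed, 4 also when estimated.

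**Figure D2:**
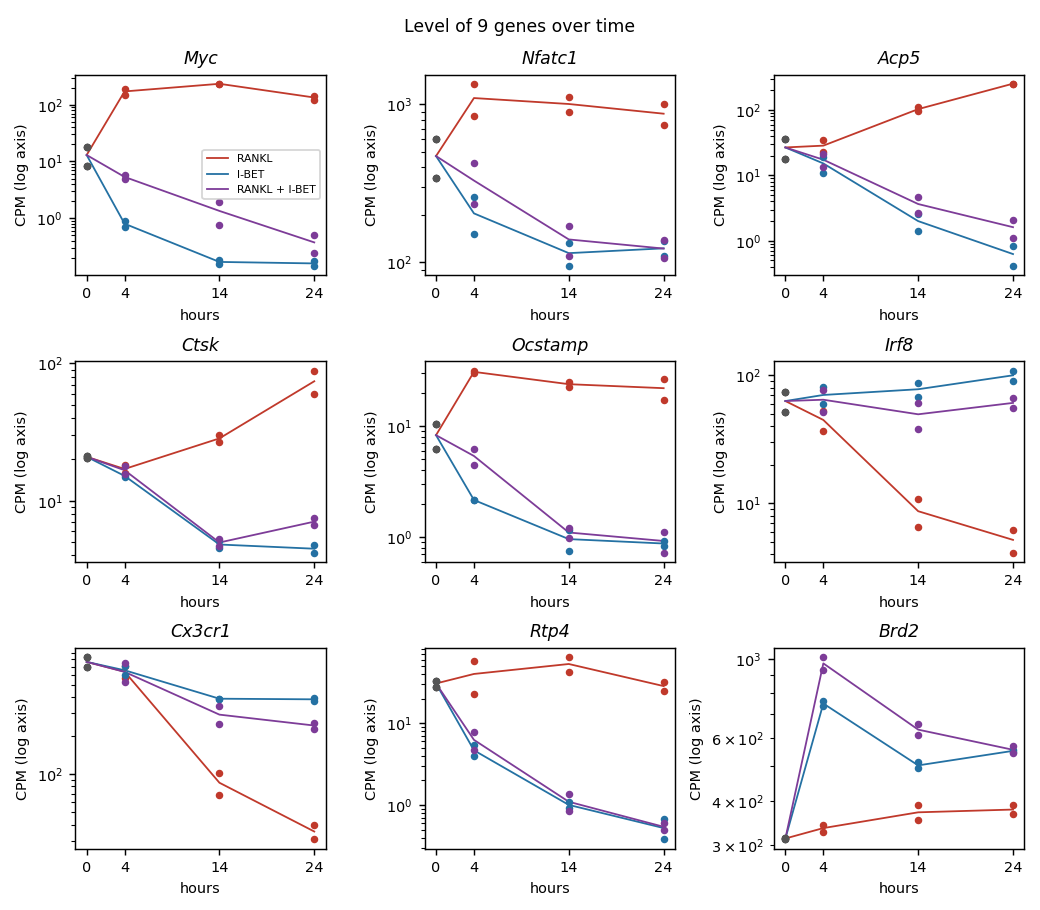
CPM of 9 genes on a log axis against hours, with 1 point per library and lines through the group means of RANKL, I-BET and both. Irf8 under RANKL fell by 3.60 on the log2 scale by 24 hours.

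The next comparison asked what the inhibitor changes, hour by hour, in cells that receive RANKL. With I-BET present for 4 hours 791 genes rose and 1037 fell against RANKL alone (2202 and 2305 with the block). The count became 962 and 817 without RANKL library 1 and 2, and 974 and 896 without combined library 1 and 2. Of these calls 43.3% were higher, and the split was 721 and 717 by limma on RPKM plus 1 and 706 and 684 on RPKM plus 0.1. Brd2 rose by 1.53 (SE 0.081, adjusted p = 3.05e-07) and Hexim1, an inhibitor of P-TEFb, rose by 1.18 (SE 0.20, adjusted p = 0.00203). Hist1h2bc, a histone gene, rose by 3.40 (SE 0.19, adjusted p = 3.42e-07) and Myc fell by 5.003 (SE 0.36, adjusted p = 3.7e-06). Nfatc1, the transcription factor that drives osteoclast formation, fell by 1.73 (SE 0.38, adjusted p = 0.00946) and Fos fell by 1.51 (SE 0.28, adjusted p = 0.00351). Bcl6 fell by 0.61 (SE 0.17, adjusted p = 0.0322) and Mmp9 fell by 2.89 (SE 0.71, adjusted p = 0.0187, on 8 combined counts). Dcstamp fell by 2.26 (SE 0.30, adjusted p = 0.000341) and Ocstamp fell by 2.52 (SE 0.28, adjusted p = 9.24e-05). Ifit3, an interferon-induced gene, fell by 3.21 (SE 0.52, adjusted p = 0.00127) and Uhrf1, a factor of replicating chromatin, fell by 0.88 (SE 0.14, adjusted p = 0.00138). The replicate block called Irf8 (0.000215), Acp5 (0.0206), Atp6v0d2 (8.12e-05) and Tnfrsf11a (1.75e-07). DESeq2 called Tnfrsf11a, and the unfiltered fit called Irf8, Acp5, Atp6v0d2 and Tnfrsf11a. Of these calls some were lost without RANKL library 1 for Nfatc1 (0.0853), Bcl6 (0.19) and Mmp9 (0.0808), RANKL library 2 for Bcl6 (0.0863) and Mmp9 (0.0606), combined library 1 for Mmp9 (0.164), combined library 2 for Nfatc1 (0.102) and Bcl6 (0.266). Of 56 calls under the naming rule, 22 were lost this way. Calls also ended for Nfatc1 with only these libraries, for Bcl6 with only these libraries, RPKM plus 1 or 0.1, for Mmp9 with only these libraries, RPKM plus 1 (log2 -0.20) and RPKM plus 0.1 (log2 -1.18). The type I interferon response list (30 genes, median -1.48) held 0 higher and 23 lower (1 and 26 within the list), below other genes (adjusted p = 5.63e-20, estimated 0.0675), while 15 passed without RANKL library 2. Next, the DNA replication list (28 genes, median -0.36) held 0 higher and 12 lower (0 and 17 within the list), below other genes (adjusted p = 7.11e-10, estimated 0.0675), while 4 passed without RANKL library 2 and 6 without combined library 1. The list of histone genes (14 genes, median 1.05) held 7 higher and 0 lower (8 and 0 within the list), above other genes (adjusted p = 4.94e-09, blocked 0.146). Camera called 10 of 18 lists, 2 also when estimated.

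With the inhibitor for 14 hours 1737 genes rose and 1801 fell against RANKL alone (3153 and 3301 with the block). Calls numbered 2451 and 2572 without RANKL library 1 and 2, and 2331 and 2154 without combined library 1 and 2. Higher calls made up 49.1%, while the split was 1734 and 1301 by limma on RPKM plus 1, 1784 and 1313 on RPKM plus 0.1, 1982 and 1964 by DESeq2, 1776 and 1773 by RLE factors, 1881 and 1724 with the CPM filter, 1012 and 879 with only these libraries, 1410 and 1162 without RANKL library 2 and 1223 and 1108 without combined library 1. Brd2 rose by 0.77 (SE 0.080, adjusted p = 1.29e-05) and Hexim1 rose by 0.88 (SE 0.20, adjusted p = 0.0059). Irf8 rose by 2.51 (SE 0.33, adjusted p = 0.000101) and Rcsd1, an actin-capping regulator, rose by 4.36 (SE 0.47, adjusted p = 1.93e-05). Myc fell by 7.52 (SE 0.43, adjusted p = 1.55e-07) and Nfatc1 fell by 2.85 (SE 0.40, adjusted p = 0.000168). Fos fell by 1.90 (SE 0.29, adjusted p = 0.000301) and Bcl6 fell by 0.84 (SE 0.17, adjusted p = 0.00268). Acp5 fell by 4.85 (SE 0.49, adjusted p = 1.05e-05) and Ctsk fell by 2.52 (SE 0.18, adjusted p = 6.9e-07). Mmp9 fell by 4.94 (SE 0.53, adjusted p = 2.78e-05) and Dcstamp fell by 2.74 (SE 0.31, adjusted p = 2.72e-05). Ocstamp fell by 4.45 (SE 0.33, adjusted p = 9.81e-07) and Atp6v0d2 fell by 5.02 (SE 0.73, adjusted p = 0.000219). Tnfrsf11a, the gene of RANK, the RANKL receptor, fell by 1.28 (SE 0.39, adjusted p = 0.0306) and Il13ra2, a decoy receptor of IL-13, was at least 175-fold lower (733 counts against 0 with a floor of 3, 95% limit 142-fold, adjusted p = 2.99e-06). Rtp4, an interferon-induced gene, fell by 5.56 (SE 0.48, adjusted p = 3.09e-06) and Ifrd2 fell by 0.99 (SE 0.19, adjusted p = 0.00198). Blocked by replicate, calls were added for Csf1r (log2 0.337, 0.00375). Limma on RPKM called Csf1r. Leaving out 1 library ended calls: without RANKL library 1 for Hexim1 (0.0652) and Tnfrsf11a (0.171), combined library 2 for Hexim1 (0.0855) and Tnfrsf11a (0.224). The naming rule gives 78 calls here, and 16 were lost this way. Further calls ended for Tnfrsf11a with RPKM plus 0.1. The type I interferon response list (30 genes, median -2.38) held 1 higher and 26 lower (1 and 28 within the list), below other genes (adjusted p = 1.18e-20, estimated 0.0544). Next, the MYC targets in ribosome biogenesis and nucleotide synthesis list (38 genes, median -0.46) held 0 higher and 25 lower (0 and 28 within the list), below other genes (adjusted p = 8.03e-11), while 16 passed without RANKL library 2 or combined library 1. Of 18 lists camera called 8, 3 also when estimated.

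At 24 hours of RANKL plus I-BET 2227 genes rose and 2072 fell against RANKL alone (3707 and 3768 with the block). With 1 library left out, calls numbered 2990 and 3899 without RANKL library 1 and 2, and 3044 and 2870 without combined library 1 and 2. While 51.8% of the calls were higher, the split was 1434 and 1556 without RANKL library 1. Brd2 rose by 0.56 (SE 0.080, adjusted p = 0.00014) and Hexim1 rose by 1.16 (SE 0.20, adjusted p = 0.000679). Irf8 rose by 3.55 (SE 0.35, adjusted p = 5.71e-06) and Hpgd, an enzyme that breaks down prostaglandins, rose by 5.12 (SE 0.70, adjusted p = 0.000102). Atp6v0a1, a proton pump subunit, rose by 1.64 (SE 0.14, adjusted p = 2.18e-06) and Myc fell by 8.49 (SE 0.46, adjusted p = 4.98e-08). Nfatc1 fell by 2.83 (SE 0.40, adjusted p = 0.000119) and Fos fell by 2.92 (SE 0.30, adjusted p = 7.95e-06). Acp5 fell by 7.30 (SE 0.54, adjusted p = 5.31e-07) and Ctsk fell by 3.39 (SE 0.18, adjusted p = 3.72e-08). Mmp9 fell by 8.08 (SE 0.60, adjusted p = 9.87e-07, on 10 combined counts) and Dcstamp fell by 2.83 (SE 0.31, adjusted p = 1.45e-05). Ocstamp fell by 4.58 (SE 0.32, adjusted p = 3.58e-07) and Atp6v0d2 fell by 6.16 (SE 0.75, adjusted p = 3.57e-05). Tnfrsf11a fell by 1.98 (SE 0.40, adjusted p = 0.00206) and Cadm2, an adhesion molecule, was at least 215-fold lower (501 counts against 0 with a floor of 3, 95% limit 174-fold, adjusted p = 2.28e-06). Rtp4 fell by 5.71 (SE 0.49, adjusted p = 1.9e-06). Calls added by the replicate block were Brd3 (0.0468). Among 80 calls of the naming rule 16 were lost with 1 library left out. The list of type I interferon response (30 genes, median -1.95) held 1 higher and 24 lower (1 and 26 within the list), below other genes (adjusted p = 3.35e-13, estimated 0.159). The osteoclast effectors list (19 genes, median -2.83) held 1 higher and 15 lower, below other genes (adjusted p = 5.54e-09). Next, the lysosome and proton pump list (26 genes, median 0.43) held 11 higher and 2 lower (13 and 2 within the list), above other genes (adjusted p = 0.00131, estimated 0.364), while 4 passed without RANKL library 1 and 6 without combined library 2. In all 12 of 18 lists passed, 1 also when estimated.

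I-BET without RANKL was compared with untreated cells to see its own effect. After 4 hours 647 genes rose and 1039 fell (2058 and 2593 with the block). The count became 758 and 631 without untreated library 1 and 2, and 996 and 516 without I-BET library 1 and 2. Of these calls 38.4% were higher, and the split was 1302 and 499 by limma on RPKM plus 1 and 1274 and 461 on RPKM plus 0.1. Brd2 rose by 1.26 (SE 0.081, adjusted p = 3.76e-06) and Hexim1 rose by 1.22 (SE 0.20, adjusted p = 0.00207). Hist1h2bc rose by 3.05 (SE 0.19, adjusted p = 3.76e-06) and Myc fell by 3.99 (SE 0.41, adjusted p = 5.8e-05). Bcl6 fell by 0.66 (SE 0.17, adjusted p = 0.0253) and Dcstamp fell by 1.98 (SE 0.31, adjusted p = 0.00145). Ocstamp fell by 1.92 (SE 0.30, adjusted p = 0.00124) and Rpph1 fell by 6.31 (SE 1.41, adjusted p = 0.0121, -1.87 without untreated library 2). Rtp4 fell by 2.72 (SE 0.40, adjusted p = 0.000967) and Uhrf1 fell by 0.77 (SE 0.14, adjusted p = 0.00397). The replicate block called Nfatc1 (3.23e-06), Fos (0.0287), Acp5 (0.0168), Ctsk (0.0264), Atp6v0d2 (2.34e-06) and Tnfrsf11a (3.23e-06). DESeq2 called Nfatc1, and the unfiltered fit called Nfatc1, Fos, Acp5, Atp6v0d2 and Tnfrsf11a. Calls that 1 library decided were lost without untreated library 1 for Bcl6 (0.206), untreated library 2 for Rpph1 (0.429), I-BET library 1 for Rpph1 (0.0692), I-BET library 2 for Bcl6 (0.234), Rpph1 (0.134) and Uhrf1 (0.0551). Of 58 calls under the naming rule, 39 were lost this way. Other alternatives ended calls for Bcl6 with only these libraries, RPKM plus 1 (log2 -0.43) and RPKM plus 0.1, for Rpph1 with only these libraries, RPKM plus 0.1 and the block without untreated library 2 (log2 -1.44). The list of type I interferon response (30 genes, median -1.15) held 0 higher and 20 lower (1 and 23 within the list), below other genes (adjusted p = 2.57e-15, estimated 0.135), while 9 passed without I-BET library 2 and 12 without untreated library 2. The DNA replication list (28 genes, median -0.41) held 0 higher and 16 lower (0 and 23 within the list), below other genes (adjusted p = 1.14e-11, estimated 0.135), while 5 passed without untreated library 2 and 5 to 7 without 3 others. Camera called 10 of 18 lists, 0 also when estimated.

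I-BET alone for 14 hours gave this split against untreated cells: 849 genes rose and 1343 fell (2318 and 2468 with the block). Calls numbered 1244 and 1229 without untreated library 1 and 2, and 1339 and 1188 without I-BET library 1 and 2. Higher calls made up 38.7%, while the split was 1243 and 797 by limma on RPKM plus 1 and 1238 and 794 on RPKM plus 0.1. Brd2 rose by 0.68 (SE 0.080, adjusted p = 6.63e-05) and Hexim1 rose by 0.70 (SE 0.20, adjusted p = 0.0326). Myo6, an unconventional myosin, rose by 3.28 (SE 0.21, adjusted p = 8.21e-07) and Myc fell by 6.23 (SE 0.49, adjusted p = 3.21e-06). Nfatc1 fell by 2.04 (SE 0.39, adjusted p = 0.00276) and Fos fell by 2.24 (SE 0.29, adjusted p = 0.000154). Bcl6 fell by 1.04 (SE 0.17, adjusted p = 0.00102) and Acp5 fell by 3.70 (SE 0.47, adjusted p = 0.000137). Ctsk fell by 2.12 (SE 0.17, adjusted p = 4.02e-06) and Dcstamp fell by 2.44 (SE 0.32, adjusted p = 0.000152). Ocstamp fell by 3.07 (SE 0.32, adjusted p = 2.44e-05) and Atp6v0d2 fell by 4.27 (SE 0.71, adjusted p = 0.00108). Tnfrsf11a fell by 1.70 (SE 0.40, adjusted p = 0.0108) and Rgs16, a regulator of G-protein signalling, fell by 6.89 (SE 0.71, adjusted p = 2.47e-05). Rtp4 fell by 4.94 (SE 0.46, adjusted p = 1.15e-05) and Fcgr2b, an inhibitory Fc receptor, fell by 2.51 (SE 0.27, adjusted p = 4.03e-05). Blocked by replicate, calls were added for Irf8 (0.0122). Calls were lost without untreated library 1 for Hexim1 (0.249) and Tnfrsf11a (0.107), untreated library 2 for Hexim1 (0.0633), I-BET library 2 for Hexim1 (0.247) and Tnfrsf11a (0.118). The naming rule gives 70 calls here, and 29 were lost this way. Calls also ended for Hexim1 and Tnfrsf11a with only these libraries. Next, the type I interferon response list (30 genes, median -2.41) held 0 higher and 28 lower, below other genes (adjusted p = 9.4e-29, blocked 0.114). The list of macrophage identity (22 genes, median -0.84) held 0 higher and 13 lower, below other genes (adjusted p = 2.2e-09, estimated 0.0864), while 8 passed without I-BET library 2. Of 18 lists camera called 10, 2 also when estimated.

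I-BET alone for 24 hours gave a larger count against untreated cells: 1203 genes rose and 1636 fell (2908 and 2896 with the block). With 1 library left out, calls numbered 1787 and 1642 without untreated library 1 and 2, and 1897 and 1731 without I-BET library 1 and 2. While 42.4% of the calls were higher, the split was 1662 and 1011 by limma on RPKM plus 1 and 1672 and 1013 on RPKM plus 0.1. Brd2 rose by 0.82 (SE 0.080, adjusted p = 9.99e-06) and Hexim1 rose by 0.96 (SE 0.20, adjusted p = 0.00426). Pacsin1, a membrane-trafficking protein, rose by 4.46 (SE 0.42, adjusted p = 6.84e-06) and Myc fell by 6.28 (SE 0.49, adjusted p = 1.76e-06). Nfatc1 fell by 1.94 (SE 0.38, adjusted p = 0.00283) and Fos fell by 2.65 (SE 0.30, adjusted p = 3.01e-05). Bcl6 fell by 0.83 (SE 0.17, adjusted p = 0.00338) and Acp5 fell by 5.36 (SE 0.54, adjusted p = 1.22e-05). Ctsk fell by 2.22 (SE 0.17, adjusted p = 1.76e-06) and Dcstamp fell by 2.55 (SE 0.32, adjusted p = 7.58e-05). Ocstamp fell by 3.22 (SE 0.32, adjusted p = 1.09e-05) and Atp6v0d2 fell by 4.38 (SE 0.71, adjusted p = 0.000684). Tnfrsf11a fell by 1.99 (SE 0.40, adjusted p = 0.00317) and Rgs16 fell by 7.81 (SE 0.77, adjusted p = 1.09e-05, on 7 I-BET counts). Mx1, an interferon-induced GTPase, was at least 16.7-fold lower (25 counts against 0 with a floor of 3, 95% limit 12.6-fold, adjusted p = 0.00281) and Msr1, a scavenger receptor, fell by 2.77 (SE 0.17, adjusted p = 3.77e-07). Calls added by the replicate block were Irf8 (5.62e-06) and Csf1r (0.0334). DESeq2 called Mmp9, the unfiltered fit called Irf8 and Mmp9, and limma on RPKM called Irf8. Of these calls some were lost without untreated library 1 for Hexim1 (0.0598), I-BET library 2 for Hexim1 (0.051). Among 72 calls of the naming rule 18 were lost this way. The type I interferon response list (30 genes, median -2.95) held 0 higher and 28 lower, below other genes (adjusted p = 2.52e-28, blocked 0.122). Next, the macrophage identity list (22 genes, median -0.65) held 1 higher and 13 lower (1 and 15 within the list), below other genes (adjusted p = 2.98e-07, estimated 0.159), while 6 passed without I-BET library 2 and 7 without untreated library 2. The list of MYC network and BET proteins (17 genes, median 0.29) held 5 higher and 1 lower (7 and 1 within the list), above other genes (adjusted p = 0.0161, estimated 0.0954), while 3 passed without untreated library 1 or I-BET library 2, and its mean of -0.10 differed in sign from its median and the test. In all 10 of 18 lists passed, 2 also when estimated.

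Over genes tested both by limma on RPKM (11556 in all) and by edgeR, the median RPKM-based change with I-BET alone was 0.114, 0.093 and 0.102 (plus 1) and 0.134, 0.109 and 0.118 (plus 0.1) at 4, 14 and 24 hours, against 0.006, 0.02 and 0.018 over the 16042 genes of edgeR. Splits by RPKM here are to be read relative to these medians.

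**Figure D3:**
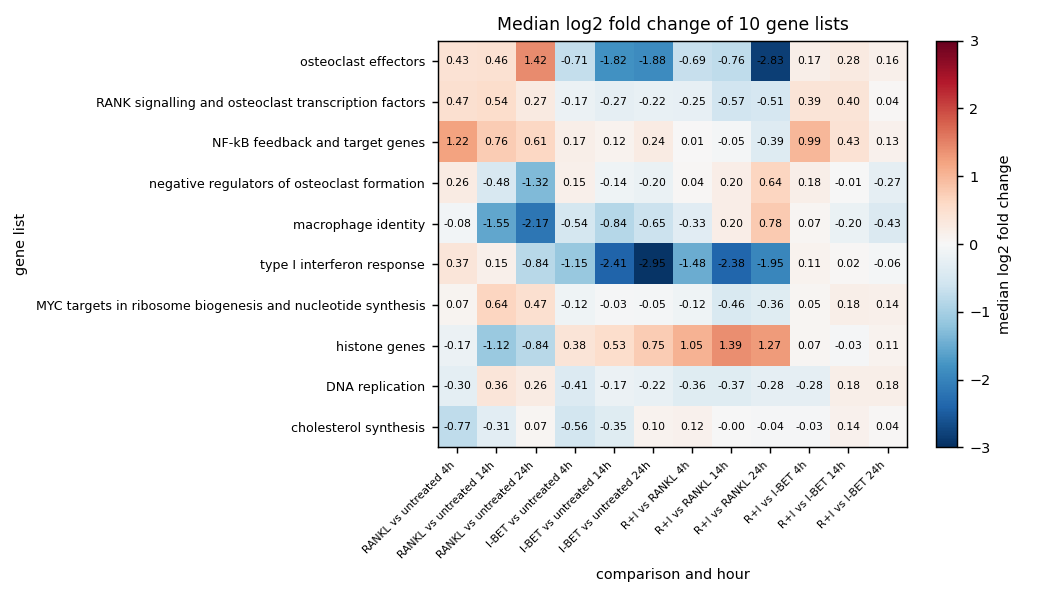
Median log2 fold change of 10 gene lists (vertical axis) in 12 comparisons (horizontal axis), with the median printed in each cell. The median of the type I interferon response list was -2.95 for I-BET at 24 hours.

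To see which RANKL response remains under the inhibitor, RANKL plus I-BET was compared with I-BET alone. At 4 hours 77 genes rose and 6 fell (331 and 162 with the block). The count became 20 and 12 without I-BET library 1 and 2, and 36 and 35 without combined library 1 and 2. Of these calls 92.8% were higher, and the split was 50 and 12 by limma on RPKM plus 1, 48 and 11 on RPKM plus 0.1 and 144 and 45 by DESeq2. Myc rose by 2.73 (SE 0.40, adjusted p = 0.00593) and Cxcl2, a chemokine, rose by 3.20 (SE 0.45, adjusted p = 0.00426). Traf1 rose by 2.83 (SE 0.33, adjusted p = 0.00112) and Il1b, the cytokine IL-1 beta, rose by 4.05 (SE 0.81, adjusted p = 0.0455, on 6 I-BET counts, 8.69 without I-BET library 1, which leaves 0 counts). Cd40, a costimulatory receptor, rose by 1.77 (SE 0.28, adjusted p = 0.00983) and Slc7a11, a cystine transporter, rose by 1.20 (SE 0.24, adjusted p = 0.0455). Smad6, an inhibitor of BMP signalling, fell by 0.94 (SE 0.18, adjusted p = 0.0363). The replicate block called Brd2 (0.00279), Nfatc1 (0.00387) and Ocstamp (0.00705). DESeq2 called Brd2 and Ocstamp, and the unfiltered fit called Nfatc1, Fos, Dcstamp and Ocstamp. Leaving out 1 library ended calls: without I-BET library 1 for Myc (0.0814), Cxcl2 (0.0956), Smad6 (0.21), Il1b (0.0587), Cd40 (0.147) and Slc7a11 (0.0956), I-BET library 2 for Myc (0.158), Cxcl2 (0.103), Smad6 (0.312), Traf1 (0.0532), Il1b (0.453), Cd40 (0.158) and Slc7a11 (0.616), combined library 1 for Smad6 (0.308), Il1b (0.298) and Slc7a11 (0.365), combined library 2 for Smad6 (0.229), Il1b (0.0832), Cd40 (0.0915) and Slc7a11 (0.073). Of 23 calls under the naming rule, 20 were lost this way. A fit of only these libraries called 0 genes. Further calls ended for Myc with RPKM plus 1 (log2 1.19), for Smad6 with RPKM plus 0.1 and no filter, for Il1b with RPKM plus 1 (log2 0.62) and RPKM plus 0.1 (log2 2.37), for Slc7a11 with RPKM plus 1 or 0.1, RLE factors and the CPM filter. The NF-kB feedback and target genes list (20 genes, median 0.99) held 11 higher and 0 lower (18 and 0 within the list), above other genes (adjusted p = 7.18e-43), while 0 passed without I-BET library 2 and 2 to 5 without 3 others. Next, the inflammatory cytokines and chemokines list (21 genes, median 1.05) held 8 higher and 0 lower (10 and 0 within the list), above other genes (adjusted p = 5.17e-20), while 0 passed without I-BET library 2 and 1 to 3 without 3 others. The list of dendritic cell and antigen presentation (16 genes, median 0.38) held 2 higher and 0 lower (3 and 0 within the list), above other genes (adjusted p = 4.25e-07, blocked 0.0783), while 0 passed without I-BET library 1 and 0 to 1 without 2 others. The integrated stress response and heat shock list (18 genes, median 0.21) held 1 higher and 0 lower, above other genes (adjusted p = 0.0159, estimated 0.701), while 0 passed without each of 4 libraries. Camera called 11 of 18 lists, 6 also when estimated.

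Under the inhibitor at 14 hours 88 genes rose and 57 fell with RANKL (573 and 483 with the block). Calls numbered 26 and 27 without I-BET library 1 and 2, and 15 and 52 without combined library 1 and 2. Higher calls made up 60.7%, while the split was 52 and 67 by limma on RPKM plus 1 and 55 and 59 on RPKM plus 0.1. Myc rose by 2.90 (SE 0.60, adjusted p = 0.039) and Traf1 rose by 3.99 (SE 0.35, adjusted p = 0.00035). Nfkb2, an NF-kB subunit, rose by 1.80 (SE 0.17, adjusted p = 0.000383) and S1pr1 fell by 2.40 (SE 0.34, adjusted p = 0.00569). Blocked by replicate, calls were added for Brd2 (0.00481), Fos (0.0065), Irf8 (0.000102), Dcstamp (0.0225), Atp6v0d2 (0.0465) and Tnfrsf11a (0.00701). DESeq2 called Brd2, Fos, Mmp9 and Dcstamp, and the unfiltered fit called Fos, Irf8, Acp5, Mmp9 and Dcstamp. Calls that 1 library decided were lost without I-BET library 1 for Myc (0.299), I-BET library 2 for Myc (0.222), combined library 1 for Myc (0.449) and S1pr1 (0.108). The naming rule gives 23 calls here, and 18 were lost this way. A fit of only these libraries called 0 genes. Other alternatives ended calls for Myc with RPKM plus 1 (log2 0.47) and RPKM plus 0.1 (log2 1.75). Next, the NF-kB feedback and target genes list (20 genes, median 0.43) held 9 higher and 1 lower (12 and 2 within the list), above other genes (adjusted p = 1.72e-12, blocked 0.0864), while 3 passed without I-BET library 2 and 3 to 5 without 3 others. The list of RANK signalling and osteoclast transcription factors (22 genes, median 0.40) held 4 higher and 0 lower (9 and 0 within the list), above other genes (adjusted p = 3.37e-11, blocked 0.0756), while 1 passed without I-BET library 1 and 1 to 2 without 3 others. Of 18 lists camera called 10, 4 also when estimated.

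Under the inhibitor at 24 hours 17 genes rose and 25 fell with RANKL (179 and 294 with the block). With 1 library left out, calls numbered 2 and 14 without I-BET library 1 and 2, and 4 and 14 without combined library 1 and 2. While 40.5% of the calls were higher, the split was 15 and 14 by limma on RPKM plus 0.1 and 11 and 3 without combined library 2. Traf1 rose by 2.61 (SE 0.33, adjusted p = 0.00905) and Egr1, an immediate early transcription factor, fell by 2.19 (SE 0.33, adjusted p = 0.0277). Fcgr3 fell by 1.69 (SE 0.21, adjusted p = 0.00905). Calls added by the replicate block were Irf8 (0.000131), Ctsk (0.0369) and Csf1r (0.00317). The unfiltered fit called Irf8, Acp5, Mmp9 and Dcstamp. Calls were lost without I-BET library 1 for Traf1 (0.225), Egr1 (0.289) and Fcgr3 (0.112), I-BET library 2 for Traf1 (0.0588), combined library 1 for Egr1 (0.153) and Fcgr3 (0.0887), combined library 2 for Egr1 (0.171). Among 12 calls of the naming rule 11 were lost this way. A fit of only these libraries called 0 genes. Calls also ended for Traf1 with RPKM plus 1 (log2 1.07). The macrophage identity list (22 genes, median -0.43) held 0 higher and 1 lower (0 and 8 within the list), below other genes (adjusted p = 4.03e-13, estimated 0.0642), while 0 passed without I-BET library 1 and 0 to 2 without 2 others. Next, the DNA replication list (28 genes, median 0.18) held 0 higher and 0 lower, above other genes (adjusted p = 2.71e-09, estimated 0.0788). The list of glycolysis (18 genes, median 0.17) held 0 higher and 0 lower, above other genes (adjusted p = 0.00306, estimated 0.596). In all 9 of 18 lists passed, 0 also when estimated.

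Whether RANKL acts differently with and without the inhibitor was tested as an interaction. Its arm without I-BET starts at hour 0, so time in culture enters it. At 4 hours edgeR called 0 genes, with 702 at an unadjusted p under 0.05, DESeq2 called 73 and the replicate block 195. None of the fixed genes passed, while the unfiltered fit called Myc and Fos and limma on RPKM plus 1 called Myc (log2 -2.39, -1.01 by edgeR). The cholesterol synthesis list (21 genes, median 0.76) held 0 higher and 0 lower (11 and 0 within the list), above other genes (adjusted p = 6.68e-22, estimated 0.252). Next, the RANK signalling and osteoclast transcription factors list (22 genes, median -0.25) held 0 higher and 0 lower (0 and 1 within the list), below other genes (adjusted p = 0.0122, estimated 0.49). Camera called 8 of 18 lists, 0 also when estimated.

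At 14 hours the interaction was called higher for 366 genes, whose RANKL effect was more positive under the inhibitor, and lower for 80 (1169 and 707 with the block). The count became 302 and 243 without untreated library 1 and 2, 241 and 339 without RANKL library 1 and 2, 275 and 219 without I-BET library 1 and 2, and 280 and 200 without combined library 1 and 2. Of these calls 82.1% were higher, and the split was 299 and 159 by limma on RPKM plus 1 and 324 and 137 on RPKM plus 0.1. Irf8 differed by 2.21 (SE 0.45, adjusted p = 0.0149) and Nt5e, an ectonucleotidase, differed by 4.46 (SE 0.42, adjusted p = 0.000149). Cx3cr1 differed by 2.74 (SE 0.32, adjusted p = 0.000457) and Serpinb6b, a protease inhibitor, differed by -3.02 (SE 0.43, adjusted p = 0.00184). Mybbp1a, a nucleolar protein, differed by -0.52 (SE 0.11, adjusted p = 0.0194). The replicate block called Nfatc1 (0.00264), Ocstamp (0.0404) and Csf1r (0.0231). The unfiltered fit called Myc, Nfatc1, Acp5 and Ocstamp, and limma on RPKM called Myc (log2 -3.49 and -2.49, -1.29 by edgeR), Mmp9 (log2 -1.75 and -3.74, -3.12 by edgeR) and Ocstamp. Of these calls some were lost without untreated library 2 for Irf8 (0.0761) and Mybbp1a (0.135), RANKL library 1 for Irf8 (0.0791) and Mybbp1a (0.0859), RANKL library 2 for Mybbp1a (0.0727), I-BET library 1 for Irf8 (0.0777) and Mybbp1a (0.08), I-BET library 2 for Mybbp1a (0.0658), combined library 1 for Mybbp1a (0.0561), combined library 2 for Irf8 (0.0969) and Mybbp1a (0.108). Of 24 calls under the naming rule, 13 were lost this way. Further calls ended for Irf8 with only these libraries, for Mybbp1a with only these libraries and no filter. The list of macrophage identity (22 genes, median 1.31) held 11 higher and 0 lower (16 and 0 within the list), above other genes (adjusted p = 4.43e-17, blocked 0.107), while 4 passed without I-BET library 2 and 4 to 7 without 5 others. The MYC targets in ribosome biogenesis and nucleotide synthesis list (38 genes, median -0.39) held 0 higher and 2 lower (0 and 16 within the list), below other genes (adjusted p = 3.67e-14), while 0 passed without untreated library 2 and 0 to 1 without 7 others. Of 18 lists camera called 9, 2 also when estimated.

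By 24 hours the interaction was called higher for 632 genes and lower for 211 (1663 and 1278 with the block). Calls numbered 647 and 541 without untreated library 1 and 2, 566 and 979 without RANKL library 1 and 2, 617 and 579 without I-BET library 1 and 2, and 570 and 594 without combined library 1 and 2. Higher calls made up 75%, while the split was 524 and 285 by limma on RPKM plus 1. Irf8 differed by 2.89 (SE 0.45, adjusted p = 0.00155) and Tgfbi passed with 1 count in 1 group, so that no size is given (adjusted p = 0.00251). Cx3cr1 differed by 3.75 (SE 0.32, adjusted p = 1.75e-05) and Cxcl10, an interferon-induced chemokine, differed by 2.07 (SE 0.36, adjusted p = 0.00292). Ctsk differed by -1.17 (SE 0.24, adjusted p = 0.00899) and Slc6a4, the serotonin transporter, differed by -5.45 (SE 1.33, adjusted p = 0.0315, on 4 combined and 4 I-BET counts). Blocked by replicate, calls were added for Nfatc1 (0.00105), Bcl6 (0.000756), Acp5 (0.016), Ocstamp (0.031) and Atp6v0d2 (1.01e-05). DESeq2 called Myc, Bcl6, Acp5 and Ocstamp, the unfiltered fit called Myc, Nfatc1, Bcl6, Acp5, Ocstamp and Atp6v0d2, and limma on RPKM called Myc, Acp5, Mmp9 (log2 -2.94 and -5.53, -2.77 by edgeR) and Ocstamp. Leaving out 1 library ended calls: without untreated library 2 for Slc6a4 (0.0503), I-BET library 1 for Slc6a4 (0.428), I-BET library 2 for Slc6a4 (0.0687), combined library 1 for Slc6a4 (0.0778), combined library 2 for Slc6a4 (0.0826). Myc passed without untreated library 1 (adjusted p = 0.0439), Ocstamp passed without untreated library 1 (adjusted p = 0.0416) and Ocstamp passed without RANKL library 2 (adjusted p = 0.0418). The naming rule gives 42 calls here, and 17 were lost this way. Other alternatives ended calls for Ctsk and Slc6a4 with only these libraries. Next, the macrophage identity list (22 genes, median 1.70) held 16 higher and 0 lower (18 and 0 within the list), above other genes (adjusted p = 1.06e-18, blocked 0.0744). The list of type I interferon response (30 genes, median 0.70) held 4 higher and 0 lower (5 and 0 within the list), above other genes (adjusted p = 1.96e-07, estimated 0.212). In all 9 of 18 lists passed, 3 also when estimated.

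**Figure D4:**
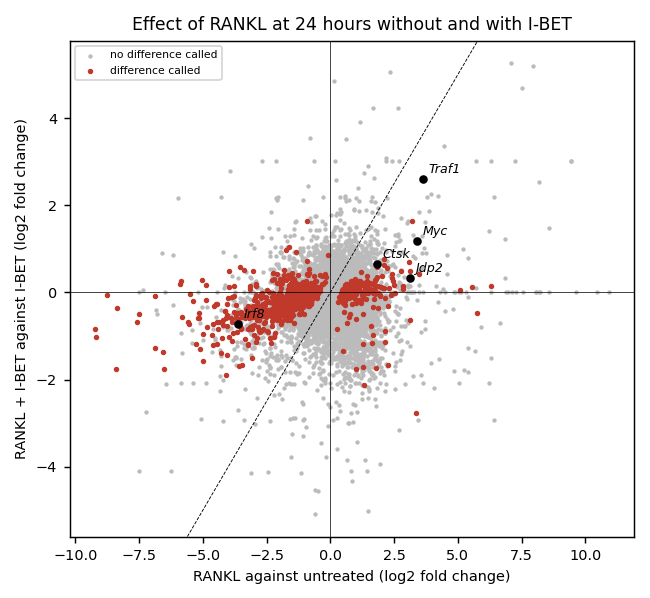
Log2 fold change of RANKL at 24 hours with I-BET (vertical axis) against that without it (horizontal axis), 1 point per tested gene. Red points mark the 843 genes whose interaction was called.

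The steps of the RANKL course show which changes come early and late. From 4 to 14 hours of RANKL 1286 genes rose and 1558 fell (3198 and 3008 with the block). With 1 library left out, calls numbered 1489 and 1762 without RANKL library 1 and 2 of 4 hours and 1770 and 1608 without RANKL library 1 and 2 of 14 hours. Acp5 rose by 1.85 (SE 0.41, adjusted p = 0.00682) and Ctsk rose by 0.74 (SE 0.16, adjusted p = 0.00659). Mmp9 rose by 3.97 (SE 0.47, adjusted p = 0.000102) and Rab15, a small GTPase, rose by 6.55 (SE 0.50, adjusted p = 4.94e-06). E2f1, a transcription factor of cell cycle entry, rose by 1.01 (SE 0.16, adjusted p = 0.000559) and Ifrd2 rose by 0.90 (SE 0.19, adjusted p = 0.00533). Cdc20, an activator of the anaphase-promoting complex, rose by 0.76 (SE 0.17, adjusted p = 0.00705) and Irf8 fell by 2.36 (SE 0.33, adjusted p = 0.000261). Csf1r fell by 0.53 (SE 0.15, adjusted p = 0.0253) and Xirp1, an actin-binding protein, fell by 6.24 (SE 0.44, adjusted p = 1.2e-06). Calls added by the replicate block were Myc (0.0435), Brd3 (0.000301), Fos (0.00782) and Atp6v0d2 (3.48e-09). DESeq2 called Fos, and the unfiltered fit called Myc, Fos and Atp6v0d2. Calls that 1 library decided were lost without RANKL library 1 of 4 hours for Ctsk (0.0708), Ifrd2 (0.067) and Cdc20 (0.0564), RANKL library 2 of 4 hours for Acp5 (0.0721) and Csf1r (0.171), RANKL library 1 of 14 hours for Ctsk (0.0505) and Csf1r (0.182), RANKL library 2 of 14 hours for Ifrd2 (0.0662) and Cdc20 (0.0753). Among 77 calls of the naming rule 33 were lost this way. Calls also ended for Ctsk and Csf1r with only these libraries. The DNA replication list (28 genes, median 0.65) held 22 higher and 0 lower (26 and 0 within the list), above other genes (adjusted p = 5.45e-17, blocked 0.0999). Next, the MYC targets in ribosome biogenesis and nucleotide synthesis list (38 genes, median 0.55) held 25 higher and 0 lower (31 and 0 within the list), above other genes (adjusted p = 5.38e-16), while 14 passed without RANKL library 1 of 4 hours and 16 without RANKL library 2 of 14 hours. The list of mitosis (25 genes, median 0.42) held 16 higher and 0 lower (17 and 0 within the list), above other genes (adjusted p = 5.94e-10, estimated 0.102), while 7 passed without RANKL library 1 of 4 hours and 7 to 10 without 3 others. Camera called 13 of 18 lists, 3 also when estimated.

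From 14 to 24 hours of RANKL 181 genes rose and 285 fell (1033 and 1674 with the block). The count became 215 and 172 without RANKL library 1 and 2 of 14 hours and 273 and 173 without RANKL library 1 and 2 of 24 hours. While 38.8% of the calls were higher, the split was 222 and 181 by limma on RPKM plus 1, 202 and 187 on RPKM plus 0.1, 288 and 279 with the CPM filter and 170 and 103 without RANKL library 1 of 24 hours. Ctsk rose by 1.38 (SE 0.16, adjusted p = 0.00051) and Rab15 rose by 3.19 (SE 0.34, adjusted p = 0.000432). Bcl6 fell by 1.05 (SE 0.17, adjusted p = 0.00416) and Il13ra2 fell by 2.74 (SE 0.33, adjusted p = 0.0015). Ifit3 fell by 2.28 (SE 0.54, adjusted p = 0.0375, -3.82 without RANKL library 1 of 24 hours) and Fcgr2b fell by 1.90 (SE 0.29, adjusted p = 0.00258). Id1, a repressor of helix-loop-helix factors, fell by 4.91 (SE 0.43, adjusted p = 0.000103, on 7 RANKL 24-hour counts). The replicate block called Myc (0.00583), Fos (0.0234), Irf8 (0.000244), Acp5 (0.000624), Mmp9 (0.00565) and Atp6v0d2 (3.01e-06). DESeq2 called Acp5 and Mmp9, the unfiltered fit called Myc, Fos, Irf8, Acp5, Mmp9 and Atp6v0d2, and limma on RPKM called Mmp9. Calls were lost without RANKL library 1 of 14 hours for Ifit3 (0.112), RANKL library 2 of 14 hours for Ifit3 (0.138), RANKL library 2 of 24 hours for Ifit3 (0.203). Mmp9 passed without RANKL library 2 of 24 hours (adjusted p = 0.0396). Of 37 calls under the naming rule, 20 were lost this way. A fit of only these libraries called 0 genes. Further calls ended for Fcgr2b with RPKM plus 1 (log2 -0.61). The type I interferon response list (30 genes, median -0.91) held 0 higher and 13 lower (0 and 24 within the list), below other genes (adjusted p = 3.49e-20, estimated 0.067), while 3 passed without RANKL library 2 of 14 hours and 3 to 5 without 2 others. Next, the macrophage identity list (22 genes, median -0.72) held 0 higher and 8 lower (0 and 12 within the list), below other genes (adjusted p = 2.31e-10, estimated 0.067), while 2 passed without RANKL library 1 of 24 hours and 3 to 5 without 2 others. The list of negative regulators of osteoclast formation (15 genes, median -0.82) held 0 higher and 5 lower (0 and 8 within the list), below other genes (adjusted p = 5.44e-09, blocked 0.176), while 3 passed without RANKL library 2 of 14 hours. The oxidative phosphorylation list (30 genes, median 0.18) held 0 higher and 0 lower, above other genes (adjusted p = 0.00538, estimated 0.756). Of 18 lists camera called 10, 2 also when estimated.

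Whether the effect of I-BET on RANKL-treated cells changes with time was tested as its value at 24 hours minus that at 4 hours. This difference was called higher for 734 genes and lower for 434 (1941 and 1573 with the block). Calls numbered 758 and 759 without RANKL library 1 and 2 of 4 hours, 735 and 868 without combined library 1 and 2 of 4 hours, 769 and 1039 without RANKL library 1 and 2 of 24 hours and 737 and 746 without combined library 1 and 2 of 24 hours. Irf8 differed by 3.03 (SE 0.46, adjusted p = 0.00102) and Hpgd differed by 5.47 (SE 0.95, adjusted p = 0.00279). Cybb, the NADPH oxidase subunit of phagocytes, differed by 3.26 (SE 0.35, adjusted p = 8.73e-05) and Myc differed by -3.49 (SE 0.55, adjusted p = 0.00137). Brd2 differed by -0.98 (SE 0.11, adjusted p = 0.000133) and Fos differed by -1.41 (SE 0.40, adjusted p = 0.0469). Acp5 differed by -6.59 (SE 0.64, adjusted p = 4.41e-05) and Ctsk differed by -3.36 (SE 0.24, adjusted p = 6.74e-06). Mmp9 differed by -5.19 (SE 1.23, adjusted p = 0.0217, on 10 combined 24-hour and 8 combined 4-hour counts) and Ocstamp differed by -2.05 (SE 0.41, adjusted p = 0.00653). Atp6v0d2 differed by -5.39 (SE 0.91, adjusted p = 0.00231) and Cadm2 passed with 0 counts in 1 group, so that no size is given (adjusted p = 0.000676). Blocked by replicate, calls were added for Nfatc1 (0.000227), Bcl6 (0.00864) and Tnfrsf11a (5.93e-05). The unfiltered fit called Nfatc1 and Tnfrsf11a. Of these calls some were lost without RANKL library 1 of 4 hours for Fos (0.11), RANKL library 2 of 4 hours for Fos (0.155), combined library 1 of 4 hours for Fos (0.118), combined library 2 of 4 hours for Fos (0.0913) and Mmp9 (0.339), RANKL library 1 of 24 hours for Fos (0.14), RANKL library 2 of 24 hours for Fos (0.0775), combined library 1 of 24 hours for Mmp9 (0.0529), combined library 2 of 24 hours for Fos (0.184) and Mmp9 (0.0574). The naming rule gives 49 calls here, and 17 were lost this way. Other alternatives ended calls for Myc with RPKM plus 1 (log2 -1.03), for Fos with RPKM plus 1 or 0.1 and RLE factors, for Mmp9 with only these libraries, for Ocstamp with RPKM plus 1 (log2 -0.51). Next, the macrophage identity list (22 genes, median 1.21) held 11 higher and 0 lower (13 and 0 within the list), above other genes (adjusted p = 8.59e-09, estimated 0.125). The list of osteoclast effectors (19 genes, median -0.95) held 0 higher and 8 lower (0 and 10 within the list), below other genes (adjusted p = 1.14e-07), while 5 passed without combined library 2 of 24 hours. In all 10 of 18 lists passed, 1 also when estimated.

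Fold changes were also compared across the 16042 tested genes between contrasts that share no library, by Pearson's r and Spearman's rho. Genes are not independent replicates, so no p is given. The I-BET effects with and without RANKL had r = 0.562, 0.589 and 0.528 and rho = 0.574, 0.522 and 0.433 at 4, 14 and 24 hours, and 1029 of 1828, 1462 of 3538 and 1823 of 4299 calls with RANKL had a call of the same direction without it. The RANKL effects with and without I-BET had r = 0.297, 0.347 and 0.166 and rho = 0.294, 0.421 and 0.195 at 4, 14 and 24 hours, and 68 of 83, 120 of 145 and 35 of 42 calls under the inhibitor had one without it.

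Genes that RANKL moved and added I-BET moved the other way were counted at each hour. Both contrasts share the RANKL libraries, so lists of equal size were also simulated for unchanged groups on shared libraries. Those lists rank noise alone, so they set no expectation for changed genes and lying above or below them decides nothing. At 4 hours 175 of 334 genes raised by RANKL were lower with I-BET added (21.6 by chance, 114 simulated). Of those lowered, 86 of 293 were higher (14.4 by chance, 117 simulated). At 14 hours these were 793 of 1333 (150 by chance, 456 simulated) and 818 of 1615 (175 by chance, 596 simulated). At 24 hours they were 792 of 1290 (167 by chance, 493 simulated) and 1010 of 1742 (242 by chance, 757 simulated). The covariance of the fold changes was -0.174, -0.457 and -0.642 against simulated values of -0.1, -0.102 and -0.109. Pearson's r was -0.391, -0.529 and -0.556 against -0.455, -0.441 and -0.48, so at 4 hours it was weaker than simulated. At 4 hours the count of lowered and then raised genes lay below the simulated mean, with the replicate block as well (382 against 539). The other 5 counts lay above it with the block. With both effects taken from libraries of different number, which share none, the covariance of log2 CPM differences was -0.0787 and -0.109 at 4 hours, -0.259 and -0.281 at 14 hours and -0.332 and -0.334 at 24 hours, against -0.13 and -0.172, -0.319 and -0.383, and -0.549 and -0.451 within a number.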

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

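The tests of poly(A) selection, of lowering by the treatments, of depth and of transcript length were chosen only after the result was seen, and so were the conditions on the spread between groups or libraries used for length, GC content and delay. With 2 libraries per group, single outlying samples were not tested and other splits were not counted.

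Differences between effects were called by a test of the difference itself. The RANKL effect differed with and without I-BET for 446 genes at 14 hours, among them Irf8 (2.21), Nt5e (4.46), Serpinb6b (-3.02), Cx3cr1 (2.74) and Mybbp1a (-0.52), with the interaction on the log2 scale in brackets. At 24 hours it differed for 843 genes, among them Irf8 (2.89), Ctsk (-1.17), Tgfbi (6.66), Slc6a4 (-5.45), Cx3cr1 (3.75) and Cxcl10 (2.07). The I-BET effect in RANKL-treated cells differed between 24 and 4 hours for 1168 genes, among them Myc (-3.49), Brd2 (-0.98), Fos (-1.41), Irf8 (3.03), Acp5 (-6.59), Ctsk (-3.36), Mmp9 (-5.19), Ocstamp (-2.05), Atp6v0d2 (-5.39), Hpgd (5.47), Cadm2 (-9.35) and Cybb (3.26). For Tgfbi and Cadm2 a group held 1 count or 0, so these fitted values rest on the prior count and are no measure of size.

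RNAs without a poly(A) tail stood high in untreated library 2: Rpph1 had 126 CPM against 3 in untreated library 1 and at most 5.8 in 18 treated libraries, and Hist1h4h, Hist1h2bk and Hist1h3e had 7.16, 3.79 and 5.11 against 0.362, 0.207 and 0.673. These 4 genes gave 19 calls of lower levels against untreated cells, 0 of them without untreated library 2 and 23 without untreated library 1. Of 45 other histone genes, 39 were at least 2-fold higher in untreated library 2 than in 1. In other groups 0 to 5 were higher in number 2 and 6 to 15 in number 1, but 30 in RANKL at 24 hours. Incomplete poly(A) selection in library 2 and lowering by the treatments stay open. Untreated library 1 lay above all treated libraries in 0 of 4 genes, but these were chosen for standing high in library 2. Without library 2, Rpph1 was still lower at 4 hours (log2 -2.19 with RANKL and -1.87 with I-BET), not called. No biological cause of a difference between both untreated libraries was tested.

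Libraries numbered 2 differed from those numbered 1 in 8974 genes, 4791 of them higher in number 2. The deeper library carried the number 1 in 5 of 10 groups, which argues against depth. Over 14970 genes the difference correlated with transcript length at -0.0901 (-0.214 to 0.0232 by group), too weakly for length to be the main cause. Over 15990 genes, 99.7% of those tested, it correlated with GC content at 0.43 (0.168 to 0.487 by group), so a GC-related step of library preparation may contribute. The design names no biological difference between the numbers, and none was tested.

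Of 22 measured macrophage genes, 16 had a called positive interaction at 24 hours: the RANKL effect was negative without I-BET and closer to 0 with it. Without untreated library 2, 14 of these 16 stayed called (not Tlr9, adjusted p = 0.0528, or Ccr2, adjusted p = 0.0743). In 14 of 16, not Itgam or Msr1, both I-BET libraries lay above both RANKL libraries, so some room to fall was left. Whether it allowed the same fold fall was not tested. A delay stays open: the RANKL effect under I-BET correlated 0.108 more with the RANKL effect at 24 than at 4 hours, which meets the bound of 0.1 set in advance for excluding a delay. By library number the difference was -0.0167 and 0.188, so it did not exceed its spread, a demand added after 0.108 was seen. A block of the RANKL programme by BET inhibition, a partial floor, a delay and time in culture since hour 0 cannot be told apart. I-BET alone lowered 13 of 22 and raised 1.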

How the results depend on the processing

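The alternatives chosen after the data were seen are named above. A count is taken as moved when it differs by more than 1.5 times. The cause was not tested unless the alternative's construction shows it.

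With the replicate block, which removes the spread between library numbers, all 18 counts moved up. At 4, 14 and 24 hours RANKL against untreated gave 2325, 5827 and 5901 and combined against RANKL 4507, 6454 and 7475. I-BET against untreated gave 4651, 4786 and 5804, combined against I-BET 493, 1056 and 473 and interaction 195, 1876 and 2941. RANKL 14 against 4 hours gave 6206, RANKL 24 against 14 hours 2707 and I-BET effect 24 against 4 hours 3514. With only the libraries of a comparison, which leaves fewer residual degrees of freedom, counts moved down. Combined against RANKL at 24 hours did not move and the 4-hour interaction rose. At 4, 14 and 24 hours RANKL against untreated gave 163, 1389 and 1668 and I-BET against untreated 723, 921 and 1674. Combined against I-BET gave 0, 0 and 0 and interaction 1, 211 and 559. Combined against RANKL gave 345 and 1891 at 4 and 14 hours. RANKL 14 against 4 hours gave 878, RANKL 24 against 14 hours 0 and I-BET effect 24 against 4 hours 576.

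DESeq2 called 1085 for RANKL against untreated at 4 hours, 189, 426 and 142 for combined against I-BET at 4, 14 and 24 hours, 73, 863 and 1267 for interaction at 4, 14 and 24 hours, 962 for RANKL 24 against 14 hours. No low-count filter gave 176, 316 and 236 for combined against I-BET at 4, 14 and 24 hours, 139 and 1286 for interaction at 4 and 24 hours, 810 for RANKL 24 against 14 hours. With untreated library 2 left out and the block, counts were 1174 for RANKL against untreated at 4 hours, 2617 for I-BET against untreated at 4 hours, 66, 1183 and 1970 for interaction at 4, 14 and 24 hours. The 4-hour interaction, with 0 calls, gave 4 by RLE size factors, 8 by the CPM filter, 5 without robust estimation, 15 by limma on RPKM plus 1 and 1 by limma on RPKM plus 0.1. The cause was not tested for these settings.

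Leaving out 1 library, which also lowers the degrees of freedom, gave ranges of 155 to 399 (RANKL against untreated, 4 hours), 1571 to 1894 (RANKL against untreated, 14 hours), 1730 to 2349 (RANKL against untreated, 24 hours), 817 to 974 (combined against RANKL, 4 hours), 2154 to 2572 (combined against RANKL, 14 hours), 2870 to 3899 (combined against RANKL, 24 hours), 516 to 996 (I-BET against untreated, 4 hours), 1188 to 1339 (I-BET against untreated, 14 hours), 1642 to 1897 (I-BET against untreated, 24 hours), 12 to 36 (combined against I-BET, 4 hours), 15 to 52 (combined against I-BET, 14 hours), 2 to 14 (combined against I-BET, 24 hours), 0 to 9 (interaction, 4 hours), 200 to 339 (interaction, 14 hours), 541 to 979 (interaction, 24 hours), 1489 to 1770 (RANKL 14 against 4 hours), 172 to 273 (RANKL 24 against 14 hours), 735 to 1039 (I-BET effect 24 against 4 hours).

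Over genes called in either contrast, a set selected for large changes, correlations at 4, 14 and 24 hours moved for the I-BET effects to r = 0.724, 0.739 and 0.678 and rho = 0.843, 0.769 and 0.696 and for the RANKL effects to r = 0.699, 0.606 and 0.527 and rho = 0.809, 0.712 and 0.63. With the block the shares of calls in the same direction became 64, 50.2 and 50.7% for the I-BET effects and 82.4, 80.3 and 79.9% for the RANKL effects, with r = 0.566, 0.593 and 0.547 and rho = 0.58, 0.527 and 0.453 for the former and r = 0.294, 0.357 and 0.197 and rho = 0.292, 0.428 and 0.215 for the latter. Genes raised by RANKL and lowered with I-BET numbered 556, 1830 and 1801 with the block and 97, 149 and 231 at 2-fold; those lowered and raised numbered 382, 1580 and 1800 and 10, 291 and 413. From libraries of different number, on log2 CPM, the covariance of both effects had means of -0.0938, -0.27 and -0.333. The cause was not tested.

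The direction with more calls turned in at least 1 alternative in 13 of 17 comparisons with calls. No call of a printed gene or list reversed. For printed genes, calls were lost in 121 of the tests with 1 library left out, 40 with only the libraries of a comparison, 14 and 13 by limma on RPKM plus 1 and plus 0.1, and 4 without a filter; the block ended 0 calls and added 57, no filter added 53 and DESeq2 20. Over all 1101 pairs of the naming rule, tests with 1 library left out ended a call 1161 times and kept 3922 outcomes, with 4 reversed. Of 45 printed list tests 24 lost their call with an estimated correlation, 7 by fry and 36 with both the estimated correlation and the block (these 24 and 12 more, given as blocked), and 0 with the block alone.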

Other observations

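The remaining RANKL response under I-BET at 24 hours correlated across 16042 genes with the RANKL response without it at r = 0.0584 (4 hours), 0.199 (14 hours) and 0.166 (24 hours), and 31, 39 and 39 of its 42 calls had the same sign there. This reference-hour comparison was chosen after the data were seen.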
